A study of Drosophila melanogaster with 2 samples.

How the data were processed

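Binding of E(var)3-9-GFP was measured by ChIP-seq in 2 biological replicates of whole embryos, grouped by the submitters' labels into 1 group. Chromatin was sheared by sonication to fragments of 200 to 800 bp, per the labels. Each replicate comes from its own biosample of the same transgenic line, per the labels, so p-values across regions describe these libraries and do not cover variation between lines or stages.

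The authors deposited region lists in assemblies dm6 and dm3, and the notes deposited with them describe lists of peaks and background made as input for IDR for each replicate, the same kind of list made from both replicates' alignments together with a control, and the joint regions that passed an IDR threshold. IDR compares the ranks of regions between replicates. The aligner, the caller and the threshold are not given in the sources used here. The signal value of a region is a score assigned by the caller in the deposited lists, larger for stronger regions, with no stated scale. It is the authors' own value and was used only to rank and describe regions. The deposited −log10 q-value of each region was read but enters no result. The summit of each region is given in the deposited lists as an offset from its start, and 4 summits over all lists lay at or past the region's end. Signal tracks, alignments and the control library are not analysed here, so no background measured in a control is given. Read depth is unknown, and no interval resting on reads is given. The 95% Wilson intervals of shares cover counting of regions only.

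The dm6 IDR peaks were identical to the 3438 strongest regions of the joint list, and the same held in dm3. Passing was therefore a cut on joint signal, and a single IDR peak need not be ranked alike or found in both replicates. Positions were read as 1-based coordinates of dm6. Genes came from the Ensembl annotation of release 115 on the same assembly (Release 6 of the genome), with 18164 genes and 23581 distinct TSSs on the 6 arms, of which 13945 genes are protein-coding, and no dm6 region ran past an arm's end. A promoter was a position within 500 bp of a TSS. Other positions were assigned to coding exon, 5'UTR, 3'UTR, noncoding exon, intron or intergenic sequence. Expected numbers per arm came from the 133647856 bases other than N.

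Replicates were compared over the 3438 strongest regions of each list by summits within 150 bp, against 1000 circular shifts along each arm. The promoter share used the same shifts. Correlations and signal differences used 100000 permutations. Arms and proximal windows were tested with exact binomial tests. Gene lists, written before the data were examined, were tested with Fisher's exact test, each against all other protein-coding genes. Lists that hold a whole class of noncoding genes were set against protein-coding genes, because a class has no other members to compare with. Of 40 lists, 39 matched genes. The 19 sequence motifs were also fixed before the data were examined. They were searched on both strands within 100 bp of each summit and in windows centred 1000 bp to either side that held no IDR peak, and separately within 500 bp of occupied and other TSSs. Adjusted p are Benjamini-Hochberg values within each family of arms, lists, motifs or annotation classes. The threshold was 0.05, and tests are two-sided unless stated.

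The genes named in the text follow a rule set before the data were examined. It takes E(var)3-9, the genes of the 20 strongest IDR peaks within 500 bp of a protein-coding TSS that both replicates matched, and the 5 strongest peaks farther from every TSS with the nearest gene. It adds up to 3 members with the strongest promoter peak for each gene list past the threshold, members of the insulator and variegation lists with a promoter peak, and the 5 genes holding the most summits. Of the tRNA, snoRNA and pseudogene lists 1 member each is printed.

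The alternatives were the 860 strongest IDR peaks, the strongest joint-list regions, each replicate alone, other distances to the TSS, a single TSS per gene, protein-coding TSSs, genes with any joint-list region as background, other overlap rules, other motif windows and shuffled sequences, and dm3. Gene list tests, motif tests, the promoter share and summit matching were tested on simulated data. Gene lists planted at 45% occupancy against 16.5% were recovered in 60 of 60 cases with 3 calls among 720 unplanted lists. The planted lists were cytoplasmic and mitochondrial ribosomal proteins and the proteasome, with 93, 73 and 48 genes, and each gene was drawn independently. Smaller lists and weaker effects were not planted, so their recovery is unknown. TATCGATA planted into 6% of 1500 shuffled windows was recovered in 5 of 5 rounds. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.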

Results

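Chromatin immunoprecipitation followed by sequencing was used to locate E(var)3-9 in embryos of Drosophila melanogaster. E(var)3-9 is a fly chromatin gene named as an enhancer of position-effect variegation, the patchy silencing of genes placed next to heterochromatin. The protein was carried with green fluorescent protein (GFP) fused to its C-terminus in a stably transformed line and was precipitated with an antibody against GFP. The single group held 2 biological replicates, numbered 2 and 3 by the submitters, each from whole embryos of mixed sex aged 0 to 24 h. The values are regions with a signal value assigned by the authors' caller, and read depth is unknown. The deposited lists are a list for each replicate with 30000 regions, a joint list called on both replicates together with 24963 regions in assembly dm6, and the 3438 joint regions that passed the authors' irreproducible discovery rate (IDR) threshold, called IDR peaks here. With 1 group there was no comparison between conditions, and the comparisons below ask where the IDR peaks lay and how far the replicates placed and ranked them alike.

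E(var)3-9-GFP was found at 3438 places on the 6 assembled arms 2L, 2R, 3L, 3R, 4 and X. The strongest lay at the promoters of CG14100 and Ugalt, a UDP-galactose transporter gene, with joint signal values of 1206 and 1114, against a median of 89.3 over all IDR peaks and a minimum of 58.2. Both replicates put these regions at their top: CG14100 had a signal of 585 in replicate 2 and 621 in replicate 3, and Ugalt 596 and 520. The median width was 420 bp, and the 3438 peaks formed 3257 separate stretches once overlapping regions were merged.

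The replicates placed their strong regions at the same sites. Of the 3438 strongest regions of replicate 2, 2408 (70.04%, 95% Wilson interval 68.5 to 71.5) had a summit of the 3438 strongest regions of replicate 3 within 150 bp. Regions shifted along their arms matched in 0.761% on average and in 1.37% at most (one-sided permutation test, p = 0.001, the smallest that 1000 shifts can give). Agreement fell with rank, from 98.4% of the regions of replicate 2 ranked 1 to 687 to 40.3% of those ranked 2751 to 3438. Of the IDR peaks, 2388 (69.5%) were matched among the 3438 strongest regions of both replicates, and 77 (2.24%) in neither. Across the 3302 IDR peaks matched in both complete replicate lists, the signals of the replicates were correlated with Spearman's rho of 0.610 and Pearson's r of 0.692 on log2 values (two-sided permutation test of rho, p = 1e-05, the smallest that 100000 permutations can give). This correlation runs across regions, which are not independent replicates. The IDR peaks are the strongest by joint signal, which was close to the sum of both replicates' signals. Choosing peaks by that sum can itself change the correlation.

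**Figure D1:**
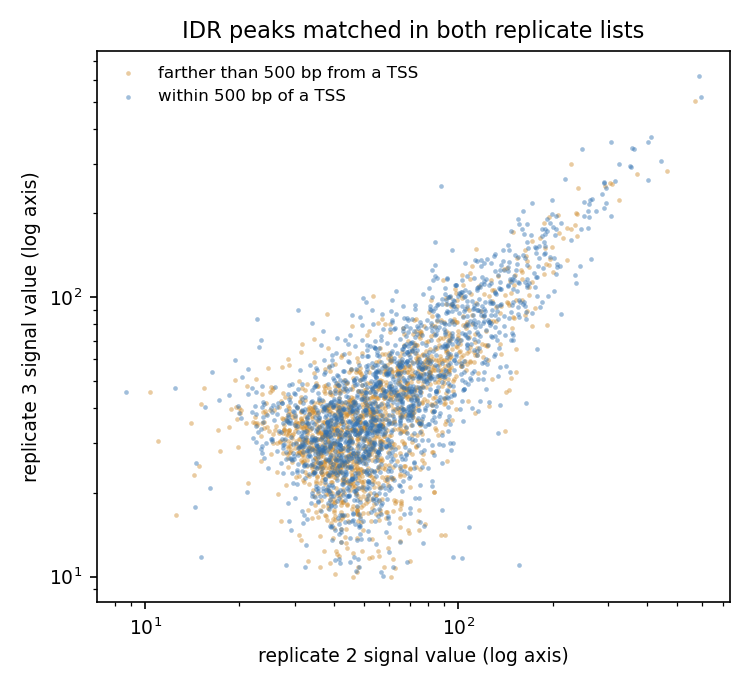
Signal value in replicate 2 (x axis, log) against replicate 3 (y axis, log), in the caller's units, for the 3302 IDR peaks matched in both replicate lists, one point per peak, coloured by distance to the nearest transcription start site (TSS). The cloud narrows toward the strongest peaks, and Spearman's rho was 0.610.

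E(var)3-9-GFP lay mainly at promoters and in introns, and hardly ever in coding sequence. Promoters, taken as positions within 500 bp of an annotated TSS, held 1852 of the 3438 summits (53.9%, Wilson interval 52.2 to 55.5). The share was 53.9% in replicate 2 and 50.3% in replicate 3 (mean 52.1% ± 2.53, SD, n = 2). Circularly shifted peaks reached 13.5% on average and 15.8% at most (one-sided permutation test, p = 0.001, the smallest that 1000 shifts can give), so that promoters were hit 3.98 times as often as in shifted positions. Introns outside promoter windows held 1136 summits (33.0%, against 39.5% of the genome) and intergenic sequence 395 (11.5%, against 27.1%). Only 4 summits (0.116%) lay in coding exons outside promoter windows, which make up 13.7% of the genome, and 18 lay in 3'UTRs. Exact two-sided binomial tests against genome share gave Benjamini-Hochberg adjusted exact p = 4.64e-211 for coding exons, 3.46e-111 for intergenic sequence and 7.04e-15 for introns. With promoter windows included, 8 summits (0.233%) lay in coding sequence, which makes up 16.7% of the genome.

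The regions of the joint list that did not pass the threshold, which are its weaker ones, leaned the same way but to a smaller degree. Promoters held 22.4% of those 21525 regions (odds ratio of IDR peaks to these 4.04, 95% interval 3.74 to 4.35, Fisher's exact test, p = 6.56e-293), and coding exons held 4.35% of them. Both shares lay between those of the IDR peaks and of the genome, where promoters make up 13.6% and coding exons 13.7%. Within the IDR peaks, promoter peaks were the stronger ones, with a median signal of 94.2 against 84.9 for the 1586 other peaks. The median rank of promoter peaks was 9.63 percentile points higher (two-sided permutation test, p = 1e-05, the smallest that 100000 permutations can give). It was 14.9 points higher among the 860 strongest, 15.1 without replicate 2 and 9.10 without replicate 3. The promoter share was 65.6% for peaks ranked 1 to 687 and 45.3% for those ranked 2751 to 3438.

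**Figure D2:**
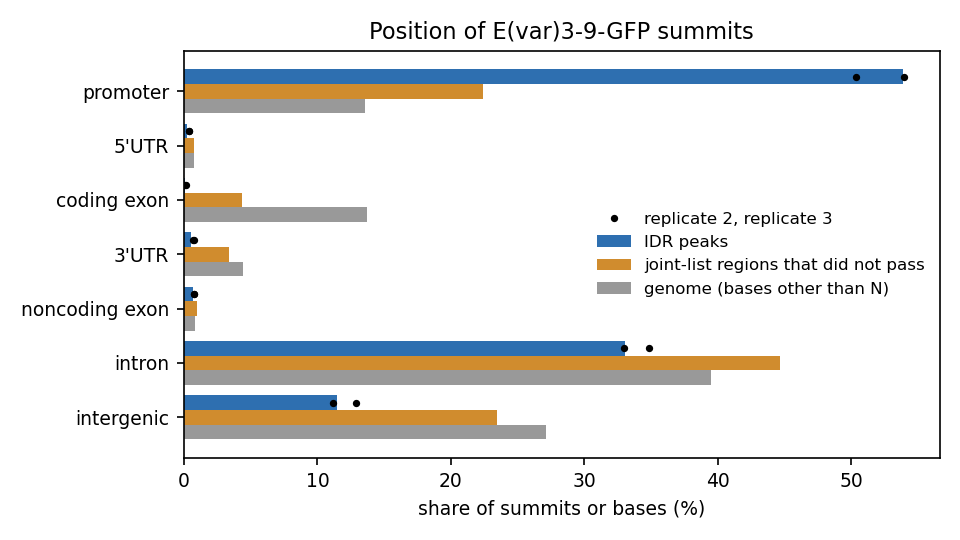
Share of summits, or of genome bases, in each annotation class (x axis, percent), for the 3438 IDR peaks, the 21525 joint-list regions that did not pass, and the genome. Black points give the 3438 strongest regions of each replicate. Promoters hold 53.9% of the IDR summits and 13.6% of the genome, and coding exons hold 0.116% and 13.7%.

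Among the 20 strongest promoter peaks matched in both replicates, CG14100 and Ugalt were followed by Art3, encoding an arginine methyltransferase, with a joint signal of 786, mRpL41, a mitochondrial ribosomal protein gene, with 768, and px (plexus) with 747. Chro, encoding the chromodomain protein Chromator of polytene interbands, had 698, with 364 in replicate 2 and 340 in replicate 3. That region lies on 3L from 22878730 to 22879072 and its summit falls in annotated 5'UTR. The peak of ph-p, a Polycomb group gene, had a signal of 643 and lay on X from 2137176 to 2137531 in an intron, 466 bp from the nearest TSS of the gene. Lon, encoding a mitochondrial protease, had 561, and Sox14, encoding a transcription factor, 519. The other genes were Tcs5, SLC5A11, CG5611, CenG1A, Pdrg1, Shc, amon, CG13390, CG31145, Tina-1 and Fkbp14, with joint signals from 504 for Fkbp14 to 709 for Tcs5.

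The strongest peaks away from every TSS lay in introns. The first, with a joint signal of 1068 (568 in replicate 2 and 503 in replicate 3), lay on 2L from 480898 to 481282, inside the span of ush, a gene for a cofactor of GATA factors, and 1405 bp from the TSS of cbt. The next lay near CG11050 with 745, CG32772 with 649, CG9663 with 571 and Trl, the gene of GAGA factor, with 557. The Trl peak lay on 3L from 14759323 to 14759706, 1534 bp from the nearest TSS. Several peaks could share a gene. The long noncoding RNA gene lncRNA:CR44357 held 16 summits over 239 kb of X, and CG1677, which lies within that span, held 14 over 125 kb. The cell adhesion gene kirre held 11 over 394 kb, the forkhead gene CHES-1-like 10 over 27.05 kb, and sbb 9 over 79.1 kb.

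E(var)3-9 itself is the gene of the tagged protein and lies on 3R from 8990645 to 8992949 on the minus strand. Both replicate lists held a region at its promoter. In replicate 2 it ran from 8992920 to 8993343 with a signal of 145 (rank 195) and a summit 183 bp upstream of the TSS, and in replicate 3 from 8992897 to 8993280 with 69.4 (rank 547) and a summit 140 bp upstream. The joint list as used here held no region within 2000 bp of the gene, and the nearest IDR summit was 32459 bp away.

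Observed counts over those expected from length ran from 0.907 on 2R (590 summits against 650) to 1.17 on the small chromosome 4 (40 against 34.2), which is largely heterochromatic. X had 627 summits against 604. In exact two-sided binomial tests, 0 of the 6 arms passed an adjusted p of 0.05. At an unadjusted p under 0.05 there was 1, arm 2R (exact p = 0.00841, adjusted exact p = 0.0505). The value on chromosome 4 turned with the setting, to 0.467 (4 summits against 8.57, adjusted exact p = 0.582) among the 860 strongest IDR peaks and to 0.905 (adjusted exact p = 0.810) without replicate 2. In replicate 3 alone, without replicate 2, there were 2, with 2R at 0.875 (adjusted exact p = 0.00212) and X at 1.10 (adjusted exact p = 0.0262).

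Sequence next to the centromeres was nearly empty of IDR peaks. The proximal 1000000 bp of arms 2L, 2R, 3L, 3R and X, which border or hold pericentric heterochromatin, contained 6 summits where 128 were expected by length (ratio 0.0468, exact two-sided binomial test, p = 2.80e-47). The 3438 strongest regions of replicate 2 had 4 there and those of replicate 3 had 9. The complete lists, weak regions included, were also low there, with ratios of 0.121 for replicate 2, 0.319 for replicate 3 and 0.182 for the joint list. How much of this sequence reads could be placed in is not given in the sources used here. The expectation rests on length alone and does not allow for the number of TSSs in these windows. Since 53.9% of IDR summits lay within 500 bp of a TSS, avoidance of this sequence cannot be told from a lack of promoters there.

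In all, 2302 of 13945 protein-coding genes (16.51%) had an IDR summit within 500 bp of a TSS, 2292 by replicate 2 and 2152 by replicate 3. Genes of ribosomal proteins and of RNA polymerase II and general factors, a list with Mediator genes, were occupied more often than other genes. Translation initiation factors did not pass (7 of 44, 15.9%, odds ratio 0.957, Fisher's exact test, adjusted p = 1). Of the 93 genes matched as cytoplasmic ribosomal proteins, 46 (49.5%) had a promoter peak against 16.3% of other protein-coding genes (odds ratio 5.03, interval 3.27 to 7.74, Fisher's exact test, adjusted exact p = 1.66e-12). RpS27 (joint signal 297), RpL34b (267) and RpL32 (211) were the strongest. The share was 50.5% by replicate 2 and 35.5% by replicate 3. Of 73 mitochondrial ribosomal protein genes, 27 (37.0%) were occupied (odds ratio 2.99, interval 1.78 to 4.93, adjusted exact p = 0.000103), led by mRpS10 (786), mRpL41 (768) and mRpS23 (651). The region of mRpS10 is the one given above for Art3, and that of mRpS23 is the one given for CenG1A. RNA polymerase II and general factors followed with 23 of 67 (34.3%, odds ratio 2.66, interval 1.53 to 4.51, adjusted exact p = 0.00114), led by Polr2B (261) and the Mediator genes MED27 (251) and MED30 (248).

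Genes of insulator proteins, which bind chromatin domain borders, had a promoter peak in 9 of 20 cases (45%, odds ratio 4.15, interval 1.52 to 11.03, adjusted exact p = 0.00734). These were Chro (698), Cp190 (269), M1BP (212), Trl (105), BEAF-32 (98.4), pita (95.5), pzg (86.9), Dref (72.2) and Clamp (67.9), with joint signals in parentheses. BEAF-32 had no matching region in replicate 3. Of 28 modifiers of variegation, 10 (35.7%) were occupied (odds ratio 2.82, interval 1.16 to 6.45, adjusted exact p = 0.0423): tefu (188), HP4 (158), HP1b (114), Trl (105), chif (101.4), Su(var)3-7 (70.7), JIL-1 (65.4), the gene of heterochromatin protein HP1a (63.9), dom (61.7) and Acf (58.8). JIL-1 encodes a histone kinase. Su(var)3-7 and the HP1a gene had no matching region in replicate 3. The call for the modifiers was lost by either replicate alone, with an odds ratio of 2.20 (adjusted exact p = 0.115) without replicate 2 and of 2.41 (adjusted exact p = 0.0765) without replicate 3, and with a single TSS per gene (odds ratio 2.35, adjusted exact p = 0.132).

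Genes of chemosensory receptors, cuticle proteins, cytochrome P450 enzymes and seminal fluid proteins were occupied less often than other genes. None of 92 cuticle protein genes, 60 gustatory receptor genes and 59 odorant receptor genes had a promoter peak (adjusted exact p = 5.96e-07, 0.000136 and 0.000207, Fisher's exact tests, upper interval bounds of the odds ratio 0.205, 0.319 and 0.325). Among 85 cytochrome P450 genes 3 did, namely Cyp6u1 (258), Cyp317a1 (65.8) and Cyp6v1 (62.001), with an odds ratio of 0.184 (adjusted exact p = 0.00114). Glutathione S-transferases, another class of detoxification genes, did not pass (3 of 35, odds ratio 0.473, adjusted exact p = 0.336). The ionotropic receptors had 1 of 60, Ir60e (58.3), and the seminal fluid proteins 1 of 47, Sfp26Ad (98.0), with adjusted exact p = 0.00114 and 0.0121. All 6 of these calls were lost in the 860 strongest IDR peaks (adjusted exact p from 0.0865 to 0.407) and among genes with a joint-list region at a TSS (adjusted exact p from 0.0559 to 0.629), although the odds ratios stayed low, at 0 to 0.214 and 0 to 0.313. None of the 111 replication-dependent histone genes had a peak (adjusted exact p = 2.05e-08), but these genes are repeated copies in which short reads are hard to place.

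Of the noncoding classes, 4 were occupied less often than the 13945 protein-coding genes, at 158 of 3261 (4.85%) for long noncoding RNAs, 8 of 269 (2.97%) for snoRNAs, 7 of 290 (2.41%) for tRNAs and 5 of 268 (1.87%) for pseudogenes. Their adjusted p were 1.29e-78, 3.21e-11, 3.26e-13 and 1.65e-13. The strongest were lncRNA:CR44463 (768), lncRNA:CR44120 (658) and lncRNA:CR44619 (479). The snRNA genes did not pass (2 of 32, odds ratio 0.337, adjusted exact p = 0.228). Within 1000 bp of a TSS the call of the snoRNA genes was lost (odds ratio 0.710, adjusted exact p = 0.0980). The snoRNA genes were led by snoRNA:Psi28S-2949 (157), the tRNA genes by tRNA:Tyr-GTA-1-8 (244) and the pseudogenes by CR15345 (122). The region of lncRNA:CR44463 is that of mRpL41, and the region of lncRNA:CR44120 is that of SLC5A11. How well reads could be placed in these noncoding classes is not known here, so few peaks cannot be told from few placed reads.

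In total 16 of 39 lists passed, 5 more often and 11 less often occupied. The Polycomb group (6 of 20, adjusted exact p = 0.195), trithorax group (7 of 21, adjusted exact p = 0.127), heat shock proteins (8 of 25, adjusted exact p = 0.104) and dosage compensation genes (4 of 8, adjusted exact p = 0.0680) did not pass in Fisher's exact test. Homeotic genes (1 of 16), segmentation genes (1 of 28) and neural development genes (1 of 32) had adjusted p of 0.570, 0.129 and 0.104 in the exact test. Restricted to genes with any joint-list region at a TSS, 5 of 35 lists passed, with cytoplasmic ribosomal proteins the 1 occupied more often (odds ratio 2.14, adjusted exact p = 0.00666). The other 4 such lists lost their call at odds ratios above 1, with insulator proteins at 2.83 (adjusted exact p = 0.187), modifiers of variegation at 2.25 (adjusted exact p = 0.387), mitochondrial ribosomal proteins at 1.94 (adjusted exact p = 0.132) and RNA polymerase II and general factors at 1.91 (adjusted exact p = 0.167). Among the 860 strongest IDR peaks, 5 lists passed and none was occupied more often. The odds ratios there were 2.19 for cytoplasmic ribosomal proteins (adjusted exact p = 0.148), 1.62 for mitochondrial ribosomal proteins (adjusted exact p = 0.598), 2.82 for RNA polymerase II and general factors (adjusted exact p = 0.0522), 3.19 for insulator proteins (adjusted exact p = 0.220) and 1.39 for modifiers of variegation (adjusted exact p = 0.871). Genes are not independent replicates, and a single peak can lie within 500 bp of several genes.

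**Figure D3:**
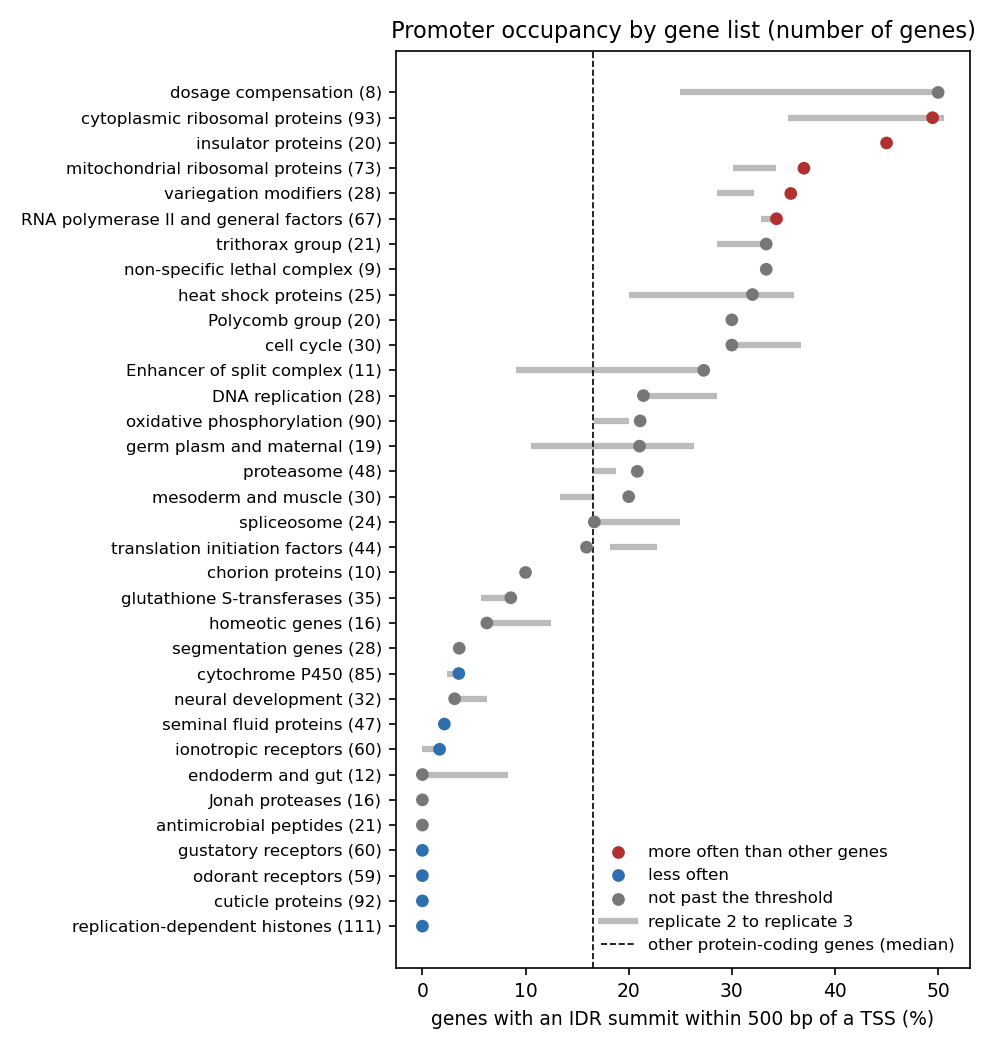
Share of genes with an IDR summit within 500 bp of a TSS (x axis, percent) for each protein-coding gene list, with the number of genes in parentheses. Points are the IDR peaks, grey bars span the values of replicates 2 and 3, and the dashed line is the median share of other protein-coding genes. Cytoplasmic ribosomal proteins stand at 49.5%, with replicates at 50.5% and 35.5%.

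The sequence under the summits was rich in A and T, and 9 of 19 motifs were more frequent in it than in its flanks. Windows of 201 bp around IDR summits had a GC content of 33.7% ± 6.22 (SD over 3438 windows), against 42.7% ± 9.46 in 6532 windows centred 1000 bp away. The DNA replication-related element TATCGATA, bound by Dref and BEAF-32, was in 3.14% of summit windows and 0.551% of flanks (odds ratio 5.85, interval 3.97 to 8.81, Fisher's exact test, adjusted exact p = 4.61e-22). It was in 5.56% of promoter peaks and 0.315% of the others, so its share was above that of the flanks at promoter peaks only. Core promoter Motif 7 was in 6.49% against 2.97% (odds ratio 2.27, adjusted exact p = 2.57e-15), with 10.04% in promoter peaks and 2.33% in the others. Motif 6 (odds ratio 2.09), the TATA box (2.03), the Motif 1 element of M1BP (2.28), runs of A (1.61), TA repeats (1.98), the su(Hw) core (1.69) and the CTCF core (1.24, adjusted exact p = 0.0493) were also more frequent. Motif 1 was in 1.94% of promoter peaks and 0.504% of the other peaks, against 0.566% of flanks. CA repeats (odds ratio 0.388) and the E-box CAGCTG (0.769) were less frequent. CAGCTG was in 9.56% of promoter peaks, close to the 9.72% of flanks, and in 5.42% of the other peaks. In all, 11 of 19 motifs passed, 9 more and 2 less frequent. The Initiator did not pass (16.7% against 17.9%, odds ratio 0.919, adjusted exact p = 0.177). Against shuffled summit windows with the same dinucleotides, CA repeats and CAGCTG were more frequent (odds ratios 2.63 and 3.62), and the TATA box (1.07, adjusted exact p = 0.484) and su(Hw) core (1.499, adjusted exact p = 0.0777) lost their call. In the 860 strongest peaks Motif 1 was less frequent than in flanks (odds ratio 0.651, adjusted exact p = 0.606), and TA repeats (1.57, adjusted exact p = 0.0884) and CAGCTG (0.842, adjusted exact p = 0.382) lost their call. Within 50 bp of the summit Motif 1 (1.65, adjusted exact p = 0.163) and the CTCF core (1.32, adjusted exact p = 0.0609) lost theirs. The GAGA repeat, bound by GAGA factor and Clamp, did not pass against flanks (3.08% against 3.66%, odds ratio 0.838, adjusted exact p = 0.177). Against shuffled windows it had the highest odds ratio of the 19 motifs (3.08% against 0.465%, odds ratio 6.80, Fisher's exact test, adjusted exact p = 5.74e-17). Flanks held it more often than shuffled windows too, so this ratio does not set summits apart from flanks. The same held for CA repeats (5.08% of flanks, 0.785% of shuffled windows) and CAGCTG (9.72% and 2.24%).

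**Figure D4:**
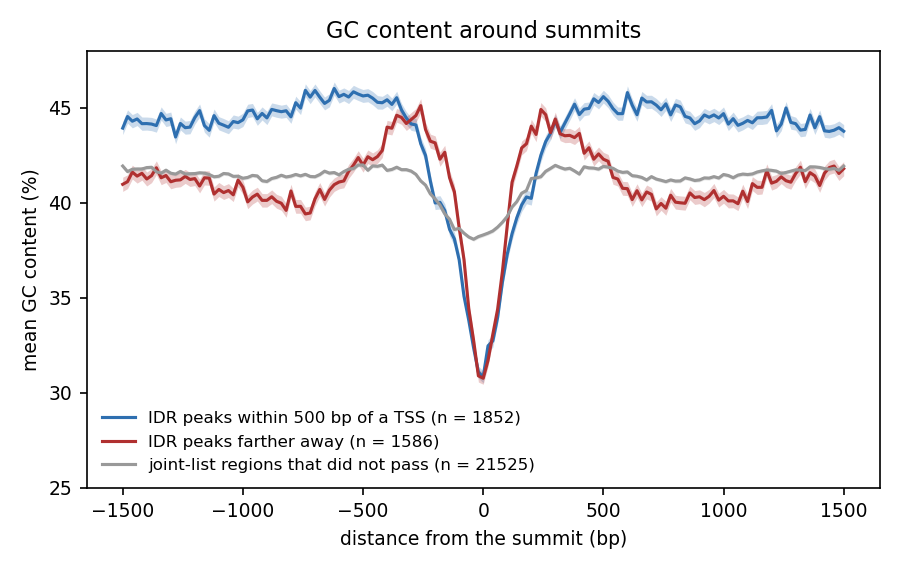
Mean GC content (y axis, percent) of windows of 21 bp by distance from the summit (x axis, bp) for IDR peaks within 500 bp of a TSS (n = 1852), IDR peaks farther away (n = 1586) and joint-list regions that did not pass (n = 21525). Bands are the standard error of the mean. At the summit the means were 30.8%, 30.8% and 38.3%.

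Occupied promoters also differed in sequence from other promoters. Among protein-coding genes, taken at a single TSS each, 2034 were occupied and 11911 were not. Motif 7 lay within 500 bp of 34.3% of occupied and 18.7% of other TSSs (odds ratio 2.26, interval 2.04 to 2.51, Fisher's exact test, adjusted exact p = 1.20e-50). TATCGATA lay near 20.4% and 10.9% (odds ratio 2.08, interval 1.84 to 2.36, adjusted exact p = 2.00e-28). CAGCTG (odds ratio 1.42), Motif 1 (1.48), Motif 6 (1.30), the heat shock element (1.66, adjusted exact p = 0.0210) and CA repeats (1.17, adjusted exact p = 0.0249) were also more frequent. Sequences matching the Initiator (odds ratio 0.763) and the TATA box (0.768) were less frequent at occupied promoters, and also within 200 bp of the TSS (0.659 and 0.664). Matches counted on either strand and at any position in the window, so they need not be working core elements, and promoter type was not tested. Windows of close genes overlap, so 1 summit and 1 motif copy can count for both, while the intervals and p-values take genes as independent. With summits within 150 bp of the TSS, 61.8% of occupied and 22.0% of other genes had a divergent TSS within 500 bp upstream. The motif comparison does not separate sequence from this arrangement. In all, 9 of 19 motifs passed, 7 more and 2 less frequent. The calls of Motif 1, the heat shock element and CA repeats were lost in the 860 strongest peaks (odds ratios 1.14, 1.31 and 1.02) and within 200 bp of the TSS (1.15, 1.55 and 0.939). The heat shock element also lost its call without replicate 2 (odds ratio 1.45, adjusted exact p = 0.117).

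The same libraries on the older assembly dm3 gave 3146 IDR peaks and a joint list of 21071 regions. In dm3, where heterochromatin scaffolds and unplaced sequence are listed, 5 IDR peaks (0.159%, Wilson interval 0.0679 to 0.372) lay on them. The dm6 lists held regions on the 6 arms alone, with none on Y or on unplaced sequence. Coordinates were not converted between the assemblies.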

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

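The tests in this part were chosen after the results were seen. The promoter region of E(var)3-9 stood in both replicate lists, with signals of 145 in replicate 2 and 69.4 in replicate 3, and was absent from the joint list, which the comparisons above rest on. Joint signals were close to the sum of both replicates' signals (median ratio 1.01 over 3302 IDR peaks), and for this region the sum was 215, a value that only 273 IDR peaks exceeded. Strong regions were not lost in general, because among the 1459 regions that ranked within the 2000 strongest of both replicates this was the 1 (0.0685%) that overlapped no joint region. Nearby regions were absent too. None of the 6 other regions of the replicate lists within 10000 bp overlapped the joint list, for which regions of similar rank give a chance of 1.15e-06. This chance is a product over single regions that takes neighbouring regions and both replicates as independent, which they need not be. In replicate 2 a run of 11 absent regions reached from 8980949 to 9014444 on 3R. With the regions at each gene's own TSS left out in the same way, 3 of 13945 protein-coding genes had so low a chance over both replicates, E(var)3-9 and its neighbours CG11975 and CG11977, which were singled out after their values were seen. Replicate 3 alone, with 1 other region, showed little (chance 0.298, as low for 3.58% of the genes). Whether a stretch around the gene was left out of the joint list stays open, because the joint list holds 1 region inside that run, 7815 bp from the TSS with a signal of 20.7, and its gap around the promoter, 19780 bp, is shorter than 3.54% of the spacings in the joint list. Extra copies of the locus carried by the transgene called for many regions in both replicates. At least as many regions within 10000 bp of the TSS were found for 49.8% of protein-coding genes in replicate 2 and for 90.2% in replicate 3, where the gene had 2 regions and the median gene 4. The value of replicate 3 goes against more regions from extra copies and that of replicate 2 is near the middle, so extra copies stay open. No biological explanation was tested.

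In dm3, 811 of 30000 regions of replicate 3 lay on heterochromatin or unplaced scaffolds, which the dm6 lists do not name, against 158 of 30000 in replicate 2 (odds ratio 5.25, interval 4.42 to 6.27, Fisher's exact test, p = 6.51e-108). A candidate explanation is that weak regions fill lists of fixed length differently in each library. Below the 3146 strongest, the counts were 801 and 154 (odds ratio 5.33, interval 4.48 to 6.38). Among the 3146 strongest regions they were 10 and 4 (odds ratio 2.50, interval 0.721 to 10.95, Fisher's exact test, p = 0.179), too few to show whether the difference is restricted to weak regions. In dm6 the proximal windows of the arms held 357 regions of the complete replicate 3 list and 135 of that of replicate 2. No biological explanation was tested.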

How the results depend on the processing

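The alternatives were all chosen before the data were examined. Of 48 recomputed values that answer a comparison, 45 kept their direction and their side of the threshold, or stayed within 1.5 times for counts. Those from the strongest joint-list regions are counted among the 45 but show nothing about stability, because these are the IDR peaks themselves. Leaving out a replicate gave 0 to 2 arms past the threshold, the 2 without replicate 2, and the cause was not tested. Lists past the threshold fell from 16 to 5 among the 860 strongest IDR peaks, and to 5 for genes with a joint-list region at a TSS, where fewer genes were tested. In the 860, odds ratios fell for cytoplasmic (5.03 to 2.19) and mitochondrial (2.99 to 1.62) ribosomal proteins, insulator proteins (4.15 to 3.19) and variegation modifiers (2.82 to 1.39) and rose for RNA polymerase II (2.66 to 2.82), and those of the less occupied lists stayed at 0.315 or below. Without replicate 2 or 3 there were 17 and 16. The promoter share was 40.8% within 250 bp and 63.8% within 1000 bp. Against shuffled windows CAGCTG (odds ratio 3.62) and CA repeats (2.63) turned from less to more frequent. Motif 1 was at 0.651 in the 860 strongest peaks and CA repeats at 0.939 within 200 bp of the TSS, both past no threshold. The ratio of observed to expected peaks turned below 1 on chromosome 4 (0.467) and X (0.960) in the 860 strongest peaks. Without replicate 2 it was 0.905 on chromosome 4 and 1.10 on X, and without replicate 3 it was 1.23 and 0.990, where only the 1.10 passed the threshold. The cause was not tested for any of these. Of 246 values for single lists, motifs and arms, 200 kept direction and call, 37 lost the call, 1 gained it and 8 turned direction. The 200 include values from the strongest joint-list regions, which could not move. These were 16 for gene lists, 11 for motifs at summits, 9 for motifs at promoters and 1 each for chromosome 4 and X. Depth limits are unknown without read counts.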

Other observations

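The test of promoter composition was chosen after the result was seen. Promoter summits lay upstream of the TSS. Of 1852, 1593 (86.0%) were upstream of the nearest TSS, with a median offset of -124.5 bp and middle values from -218 to -62 bp. For 729 of them (39.4%), TSSs of at least 2 protein-coding genes lay within 500 bp, as at Art3 and mRpS10. A hypothesis set before the count was that promoters between divergent genes are occupied more often. Counting only summits within 150 bp of a gene's own 5'-most TSS, 649 of 1051 occupied genes (61.8%) had a divergent TSS within 500 bp upstream, against 2834 of 12894 other genes (22.0%; odds ratio 5.73, interval 5.02 to 6.55, Fisher's exact test, p = 1.59e-153). Part of this may come from 1 summit counting for both genes of a close pair.

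Genes with many summits tended to be long, which was another hypothesis set before the test. Across 1293 protein-coding genes with a summit in their span, span and number of summits had Spearman's rho of 0.466 (two-sided permutation test, p = 1e-05, the smallest that 100000 permutations can give). Per 100 kb, CHES-1-like had 37.0 summits and CG14434, singled out after its values were seen, had 45.8 over 15.3 kb, against 2.79 in kirre.

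The AT-rich sequence under the summits is sharply centred. The GC content of IDR summit windows differed from that of their flanks by -8.81 ± 0.159 percentage points (SE) on average, and 83.2% of the windows were poorer than their flanks. Away from TSSs, GC rose from 30.8% at the summit to 45.1% at 260 bp upstream and 44.6% at 260 bp downstream by coordinate, above the 39.4% found 740 bp upstream. Of 2080 sequences of 6 bases, compared after the data were seen, 512 were more frequent and 1088 less frequent at summits, led by TTAAAA (55.8% against 27.4%). Not all of the more frequent ones were made of A and T alone. ACAGTG was in 19.4% against 7.52% (odds ratio 2.97) and AGTGTA in 17.2% against 6.71% (odds ratio 2.89), both singled out after their values were seen. AGTGTA was in 22.0% of IDR peaks away from TSSs and 13.1% of promoter peaks. Promoter composition alone is argued against, because IDR peaks away from TSSs differed by -6.41 ± 0.205 points (SE), against -2.27 ± 0.0724 for regions away from TSSs that did not pass. A GC bias of the libraries or of the calling stays open, since joint-list regions that did not pass also differed from their flanks by -2.91 ± 0.0675 points, a size between the bounds set beforehand for and against such a bias. A preference of the tagged protein for AT-rich DNA predicted a lower GC at stronger peaks. The correlation of signal and GC met that prediction but was close to 0 (Spearman's rho -0.0335, two-sided permutation test, p = 0.0488), with 33.5% GC in the 687 strongest and 34.2% in the 687 weakest IDR peaks. It ran only within the IDR peaks, which are the strongest joint regions, so it cannot show how much a preference explains. Across that cut, mean GC was 33.7% at IDR summits and 38.5% at regions that did not pass. A preference stays open.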
